A study of Mus musculus with 8 samples.

How the data were processed

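RNA sequencing was done on bone marrow cells of C57BL/6 mice, 4 months old per the labels, that carry JAK2 V617F on 1 allele and are labelled Plek2+/+ or Plek2-/-. TER119-positive erythroblasts were purified from bone marrow, and Kit-positive cells were purified from its lineage-negative fraction. Total RNA was extracted with TRIzol, libraries followed a standard Illumina protocol, and sequencing was done on an Illumina HiSEQ4000. The authors' processing notes name cutadapt 1.13, STAR 2.5.2a, HTSeq 0.6.1pl, DESeq2 1.14.1 and the mouse genome build mm10. The gene annotation, the strand setting and the role of each tool are not given in the sources used here.

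The deposited table of raw counts holds 23337 genes by symbol in 8 libraries, 2 in each of 4 groups, and its unit is counts (whole numbers of reads per gene). The second deposited table holds normalized signal, which was checked to equal the raw counts divided by 1 size factor per library; it was used only to read those size factors. Gene positions come from GENCODE vM21 on GRCm38, which is mm10, with RefSeq symbols and synonyms for renamed genes; 23080 genes (98.9%) were placed. Library totals ran from 16038035 to 23521726 counts, and 3 counts, the most that a count of 0 allows, equal 0.128 to 0.187 counts-per-million (CPM). Replicate libraries differed by more than counting error in each group (chi-square per degree of freedom 5.92 to 16.5), so no group holds 1 library listed under both numbers. Reads are not marked by molecule, so limits from counts cover counting error only.

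Genotype effects were tested in each population by itself with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with default settings, and quasi-likelihood fits with genotype as the term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 with no fold minimum. Positive values are higher in libraries labelled Plek2-/-. The biological coefficient of variation was 8.12% in erythroblasts and 7.17% in progenitors. The interaction (the genotype effect in erythroblasts minus that in progenitors) and the population contrast in Plek2+/+ were taken from 1 fit of all 8 libraries with 4 groups, where it was 7.62%. CPM values of Plek2, Jak2 and the sex-linked genes in the label check are on library totals; those of other genes are on TMM-scaled totals. Folds are 2 to the power of the fitted log2 fold change.

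The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The 29 lists cover red cell, stem cell and other blood lineages, JAK2-STAT5, PI3K-Akt, p53, interferon, inflammation, actin, thrombosis, cell cycle, stress, cholesterol, hypoxia and ribosomal genes, the neighbours of Plek2, mitochondrially encoded genes and sex-linked genes. The mitochondrially encoded genes were not analysed here, and the sex-linked list was described without a set test (4 of 6 tested genes higher and 1 lower in libraries labelled Plek2-/- in either population). The other 27 lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry (limma 3.58.1) stand beside it. With an estimated correlation camera called 0 lists in each comparison, also in the population contrast, where 24 of 25 heme genes were called higher. The lack of a call in that setting therefore does not decide whether a list shifted. Fry called 22 of 27 lists in the population contrast but 0 in either genotype comparison and 0 for the interaction. For neutrophil genes the estimated correlation was 0.771 in erythroblasts, 0.815 in progenitors and 0.745 for the interaction. These lie far above the preset 0.01, so camera p-values at the preset can be far too small for such lists. Counts "adjusted over the list alone" apply the Benjamini-Hochberg correction within a list.

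Named genes are Plek2, then in each genotype comparison the 10 largest rises and 10 largest falls among called genes with a mean count of at least 20 and both libraries of one genotype above both of the other. Symbols of unplaced gene models and receptor segments were left out. To these were added, from each list, the 2 called genes with the lowest adjusted p or, where none was called, the most abundant member. For the interaction the 5 highest and 5 lowest genes were taken, and for the population contrast only the list members. A few genes that the rule picks are not reported here. Overlap between populations and calls near Plek2 were tested with two-sided Fisher's exact tests, and distances to Plek2 on chromosome 12 with a one-sided permutation test of 100000 resamples in R. These tests treat genes as independent units, though genes of a library can move together.

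The test was checked on simulated data: genes shifted by 2-fold were recovered at 95.5% in erythroblasts, 91.0% in progenitors and 80.6% for the interaction, and unchanged genes made up 6.45%, 3.26% and 3.29% of the calls. Simulated genes varied independently, each with the spread typical of its abundance, and shifted genes had a mean count of at least 20. Genes of the real libraries can move together, so these shares need not hold for them. Alternatives were RLE factors, library sizes only, the authors' size factors, no low-count filter, a filter at 1 CPM, DESeq2 1.42.0, limma-voom, a replicate block, all 8 libraries in 1 fit, a log2 fold change of at least 1, globin genes left out, both genotypes averaged, other windows around Plek2, and leaving out each library in turn. A crossed replicate block and leaving out genes on X and Y or on chromosome 12 were chosen after seeing the data. The replicate numbers in the labels are not known to pair samples, so the block stands only among the alternatives. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.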

Results

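Messenger RNA levels were measured by RNA sequencing in bone marrow cells of mice that carry 1 activated copy of the kinase gene Jak2 (JAK2 V617F/+), the change that drives red cell overproduction in polycythemia vera. The mice were labelled either Plek2+/+ or Plek2-/-. Plek2 encodes pleckstrin-2, a protein with domains that bind membrane phosphoinositides, which acts in erythroblasts downstream of JAK2 and on the actin cytoskeleton. A pair of cell populations was purified: TER119-positive erythroblasts, the nucleated precursors of red cells, and lineage-negative Kit-positive stem and progenitor cells, called progenitors from here on. Each of the 4 groups held 2 libraries. Total counts were 21168532 and 19975810 in Plek2+/+ erythroblasts, 16760897 and 19399425 in erythroblasts labelled Plek2-/-, 16038035 and 22347640 in Plek2+/+ progenitors, and 19379428 and 23521726 in progenitors labelled Plek2-/-. A count of 0 at these depths allows up to 3 counts, or 0.128 to 0.187 counts-per-million (CPM) depending on the library. This limit covers counting error only. The labels do not say whether the libraries of a group came from separate mice, so each p-value refers to the spread between samples.

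The first question was whether the libraries matched their genotype labels. Plek2 lies on chromosome 12 from 78888691 to 78906964 (GRCm38), on the minus strand. Erythroblasts labelled Plek2-/- held less Plek2 RNA than Plek2+/+ erythroblasts but did not lack it: 616 and 781 reads against 1770 and 1894, or 38.5 ± 2.48 CPM (SD, n = 2) against 89.2 ± 7.92 CPM (SD, n = 2). In progenitors the order was opposite. Those labelled Plek2-/- held 130 and 173 Plek2 reads, or 7.03 ± 0.457 CPM (SD, n = 2), and the Plek2+/+ progenitors held 29 and 21, or 1.37 ± 0.614 CPM (SD, n = 2). The log2 fold change of Plek2 was -1.21 in erythroblasts (SE 0.11, 2.32-fold lower, edgeR adjusted p = 9.92e-05) and 2.47 in progenitors (SE 0.28, 95% confidence interval 1.83 to 3.11, 5.55-fold higher, edgeR adjusted p = 0.00253). The progenitor value runs against the genotype label. The part of Plek2 that was deleted is not stated, and counts per gene do not show where in the gene the reads lie.

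Sex-linked genes separated the genotypes completely. Xist, the RNA that coats the inactive X chromosome of female cells, stood at 1956 ± 134 CPM in Plek2+/+ erythroblasts and 3950 ± 126 CPM in Plek2+/+ progenitors (SD, n = 2 each), against 2.66 and 2.85 CPM in the libraries labelled Plek2-/-. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d showed the opposite pattern: Ddx3y stood at 192 ± 28.7 CPM in erythroblasts and 158 ± 4.00 CPM in progenitors labelled Plek2-/- (SD, n = 2 each), against 0.121 and 0.201 CPM in Plek2+/+. Thus in 8 of 8 libraries the Plek2+/+ label went with a female pattern and the Plek2-/- label with a male pattern. Sex and Plek2 genotype cannot be separated in any genotype comparison of this series. Plek2+/+ and Plek2-/- name the labels of the libraries here and from here on, not a genotype shown by the counts. Jak2 itself had 219 and 242 CPM in the Plek2+/+ erythroblasts and 207 and 231 CPM in those labelled Plek2-/-.

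**Figure D1:**
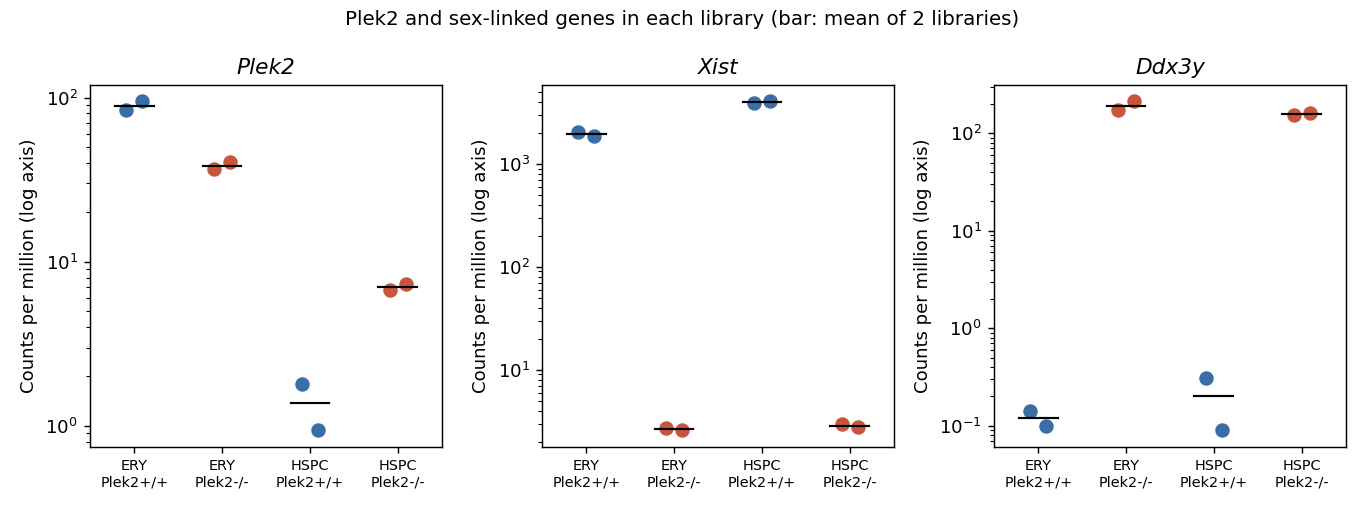
CPM of Plek2, Xist and Ddx3y (log axis) in the 8 libraries, by group (ERY, erythroblasts; HSPC, progenitors); each point is 1 library and each bar the mean of 2. Plek2 is lower in erythroblasts labelled Plek2-/- (38.5 against 89.2 CPM) and higher in progenitors labelled Plek2-/- (7.03 against 1.37 CPM), while Xist and Ddx3y separate the genotype labels in both populations.

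The comparison of erythroblasts asks how gene expression differs between the Plek2 labels in the cells in which JAK2 drives red cell production. Most called genes were lower in the libraries labelled Plek2-/-, among them 19 of 28 neutrophil, 8 of 19 primary granule, 7 of 22 mast cell, basophil and eosinophil, and 8 of 23 B cell genes. Camera called these 4 lists with its preset correlation but not with an estimated one (adjusted p = 0.494 each). The eosinophil peroxidase gene Epx stood at 308 ± 28.6 CPM in libraries labelled Plek2+/+ and 147 ± 5.01 CPM in those labelled Plek2-/- (SD, n = 2 each), and the neutrophil granule gene Lcn2 at 527 ± 39.5 and 308 ± 29.0 CPM (SD, n = 2 each). No member of the heme, red cell membrane or erythroid transcription factor lists passed the test. In all, 348 of 12241 genes passed the edgeR test, 22 higher and 326 lower in libraries labelled Plek2-/-, of which 12 lie on X or Y. The change was over 2-fold in 9 of the higher and 33 of the lower genes.

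Neutrophil genes gave the clearest shift in erythroblasts. Of 28 tested, 19 fell and 0 rose, and 26 fell when adjusted over the list alone. Their median log2 fold change was -0.66 (quartiles -0.85 to -0.54, camera adjusted p = 3.08e-33, and 0.494 with an estimated correlation). Ifitm6 fell 1.83-fold (edgeR adjusted p = 0.00388) and Lcn2 1.71-fold (edgeR adjusted p = 0.00430). The list took 1.78% ± 0.129 of all counts in Plek2+/+ and 1.22% ± 0.0976 in Plek2-/- erythroblast libraries (SD, n = 2 each). Primary granule genes, which mark earlier granulocytic cells, had 8 of 19 lower and 0 higher (16 lower adjusted over the list alone; median -0.44, camera adjusted p = 4.39e-13, and 0.494 with an estimated correlation). Examples are Cebpe, a granulocyte transcription factor, at 1.57-fold lower and Serpinb1a, an inhibitor of neutrophil proteases, at 1.46-fold lower.

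Of 22 mast cell, basophil and eosinophil genes 7 fell and 0 rose (10 fell adjusted over the list alone; median -0.61, camera adjusted p = 1.08e-13, and 0.494 with an estimated correlation). Epx fell 2.10-fold (edgeR adjusted p = 0.000120), Prg3 2.01-fold (edgeR adjusted p = 0.00609) and the eosinophil ribonuclease gene Ear6 2.43-fold (edgeR adjusted p = 0.00768). Of 23 B cell genes 8 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.76, camera adjusted p = 1.54e-11, and 0.494 with an estimated correlation). Rag1, which recombines antigen receptor genes, fell 2.19-fold, and the B cell kinase gene Blk fell 2.31-fold. The exception was Igj, the joining chain of secreted antibodies made by plasma cells, which rose 3.47-fold from 14.1 ± 3.13 to 48.7 ± 7.80 CPM (SD, n = 2 each; edgeR adjusted p = 8.14e-05). The T and NK cell list had 1 of 18 lower, the interleukin-7 receptor gene Il7r at 1.72-fold (also 1 adjusted over the list alone; median -0.47, camera adjusted p = 0.0138, and 0.494 with an estimated correlation).

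Some actin and adhesion genes were called lower beside the neutrophil genes (median -0.66). Of 49 actin and cofilin pathway genes 9 fell and 0 rose (21 fell adjusted over the list alone; median -0.28, camera adjusted p = 5.55e-10, and 0.494 with an estimated correlation). These include Coro1a, an actin-binding protein of white blood cells, at 1.55-fold lower, and the hematopoietic GTPase gene Rac2, at 161 ± 0.821 against 116 ± 1.18 CPM (SD, n = 2 each; edgeR adjusted p = 0.0146). Of 34 thrombosis and adhesion genes 8 fell and 0 rose (17 adjusted over the list alone; median -0.33, camera adjusted p = 1.91e-07, and 0.494 with an estimated correlation). The named members were the urokinase receptor gene Plaur, 1.62-fold lower, and Padi4, an enzyme of neutrophil extracellular traps that also belongs to the neutrophil list, 1.63-fold lower. Hypoxia and glycolysis genes had 2 of 27 lower, Pkm2 at 1.57-fold and Hk2 at 1.61-fold (7 adjusted over the list alone; median -0.24, camera adjusted p = 0.00218, and 0.4996 with an estimated correlation).

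No red cell list was called as shifted in erythroblasts, though most heme and membrane genes had positive values (22 of 25 and 20 of 26). The heme list nonetheless took 8.69% ± 0.149 of counts in Plek2+/+ and 7.57% ± 0.392 in Plek2-/- libraries (SD, n = 2 each). Of 25 globin, heme and iron genes 0 passed the edgeR test, 3 had an unadjusted p below 0.05, and DESeq2 called 2 and limma-voom 0 (median 0.06, camera adjusted p = 0.0738). Adult beta globin, listed as Beta-s, stood at 60772 ± 2766 CPM in Plek2+/+ and 49014 ± 3875 CPM in Plek2-/- (SD, n = 2 each; log2 -0.31, SE 0.19, edgeR adjusted p = 0.489), while the adult globin symbols Hba-a1 and Hbb-b1 are listed at 0 in each library. Of 26 red cell membrane genes 0 were called, 3 had an unadjusted p below 0.05, and DESeq2 called 0 and limma-voom 1 (1 fell adjusted over the list alone; median 0.05, camera adjusted p = 0.193); the anion exchanger Slc4a1 had a log2 fold change of 0.09 (SE 0.15, edgeR adjusted p = 0.850). The 25 erythroid transcription factors and signalling genes gave 0 calls, 2 at an unadjusted p below 0.05 and 0 with DESeq2 or limma-voom (median 0.01, camera adjusted p = 0.653), with E2f2 at 0.04 (edgeR adjusted p = 0.916). Of 36 late maturation genes only Rac2 fell (1 rose and 1 fell adjusted over the list alone; median -0.0023 with camera pointing up at adjusted p = 0.987, and the median changes sign with library sizes only). Camera called the heme and membrane lists higher without Plek2+/+ replicate 2 (adjusted p = 0.00344 and 0.0141) and without Plek2-/- replicate 1 (adjusted p = 0.0216 and 0.0195).

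Growth and signalling lists moved little in erythroblasts. S phase genes had a median of 0.10 (0 of 32 called by edgeR, 3 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom, 0 adjusted over the list alone, camera adjusted p = 0.00375, and 0.747 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.08 (0 of 73 called by edgeR, 2 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom, 0 adjusted over the list alone, camera adjusted p = 0.00833, and 0.494 with an estimated correlation). The G2 and M phase list had 0 of 32 called, 0 at an unadjusted p below 0.05 and 0 by either other tool (median 0.0064, with the opposite sign under the authors' size factors, camera adjusted p = 0.653); Mki67 stood at 0.14 (edgeR adjusted p = 0.744). The JAK2-STAT5 list had 2 of 32 lower, Plek2 itself and the interleukin-4 receptor gene Il4ra at 1.45-fold (3 adjusted over the list alone; median -0.06, camera adjusted p = 0.151). In the p53 and apoptosis list of 33, the cell cycle inhibitor Cdkn1a rose 1.89-fold and the death receptor Fas fell 2.02-fold (3 rose and 1 fell adjusted over the list alone; median 0.04, camera adjusted p = 0.290).

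Other lists held single calls in erythroblasts. Ptgs2, which makes prostaglandins, rose 2.55-fold within an inflammation list of 31 (1 rose and 4 fell adjusted over the list alone; median -0.17, camera adjusted p = 0.152). Chac1, a glutathione-degrading enzyme of the integrated stress response, rose 2.14-fold from 14.7 ± 7.06 to 31.7 ± 4.43 CPM (SD, n = 2 each; 1 of 32 in its list, also adjusted over the list alone; median 0.05, camera adjusted p = 0.172). Lgmn, a lysosomal protease gene on chromosome 12, rose 2.05-fold from 69.3 ± 2.33 to 142 ± 6.79 CPM (SD, n = 2 each; edgeR adjusted p = 8.14e-05), and was the 1 call among 30 monocyte and macrophage genes (2 adjusted over the list alone; median 0.04, camera adjusted p = 0.224). In the cholesterol list of 23, 2 fell, among them the mevalonate pathway gene Mvd at 1.87-fold (2 adjusted over the list alone; median -0.0068, camera adjusted p = 0.445). Further named rises were Rgs1 (2.18-fold) and Jkamp (1.94-fold). Further named falls were Stfa3 (3.77-fold), Fam20c (2.90-fold), Emid1 (2.53-fold), Col5a3 (2.43-fold), Mcam (2.37-fold) and Dhrs7 (2.35-fold).

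The remaining lists gave 0 edgeR calls in erythroblasts, over all genes and adjusted over the list alone. Stem cell genes had a median of -0.27 (28 tested, 7 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom, camera adjusted p = 0.0614), with Lmo2 at 0.00. Megakaryocyte genes had a median of 0.0064 and a negative camera direction (30 tested, 3 at an unadjusted p below 0.05, 0 by the other tools, camera adjusted p = 0.911), with Thbs1 at 0.06. For PI3K-Akt and FoxO genes the median was -0.14 (32 tested, 7 at an unadjusted p below 0.05, 0 by the other tools, camera adjusted p = 0.0614), with the catalase gene Cat at -0.15. Interferon response genes stood at -0.07 (40 tested, 3 at an unadjusted p below 0.05, 0 by DESeq2 and 1 by limma-voom, camera adjusted p = 0.245), with Rsad2 at -0.03. Endothelial and stromal genes stood at -0.11 (19 tested, 2 at an unadjusted p below 0.05, 0 by the other tools, camera adjusted p = 0.653), with Col1a1 at -0.11.

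In all, 10 of 27 lists passed camera with its preset correlation in erythroblasts, 0 with an estimated correlation and 0 with fry, whose lowest adjusted p was 0.245. The number of called genes rested on single libraries: 34 and 25 without Plek2+/+ replicate 1 or 2, and 995 and 119 without replicate 1 or 2 labelled Plek2-/-. Of the 40 called genes that the rule for named genes picks in erythroblasts, 13 remained called without any 1 library, among them Plek2, Igj, Lgmn, Dhrs7, Ifitm6, Lcn2, Rag1 and Epx. Camera no longer called T and NK cell genes (adjusted p = 0.0929) or hypoxia genes (adjusted p = 0.0549) without Plek2-/- replicate 2, nor S phase genes without it (adjusted p = 0.0853) or without Plek2+/+ replicate 1 (adjusted p = 0.221). It called the stem cell, megakaryocyte, monocyte, PI3K-Akt, interferon, inflammation, G2 and M phase, ER stress, cholesterol and chromosome 12 lists only with some 1 library left out, at adjusted p from 4.07e-06 for interferon genes without Plek2-/- replicate 1 to 0.0485 for cholesterol genes without Plek2+/+ replicate 1.

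**Figure D2:**
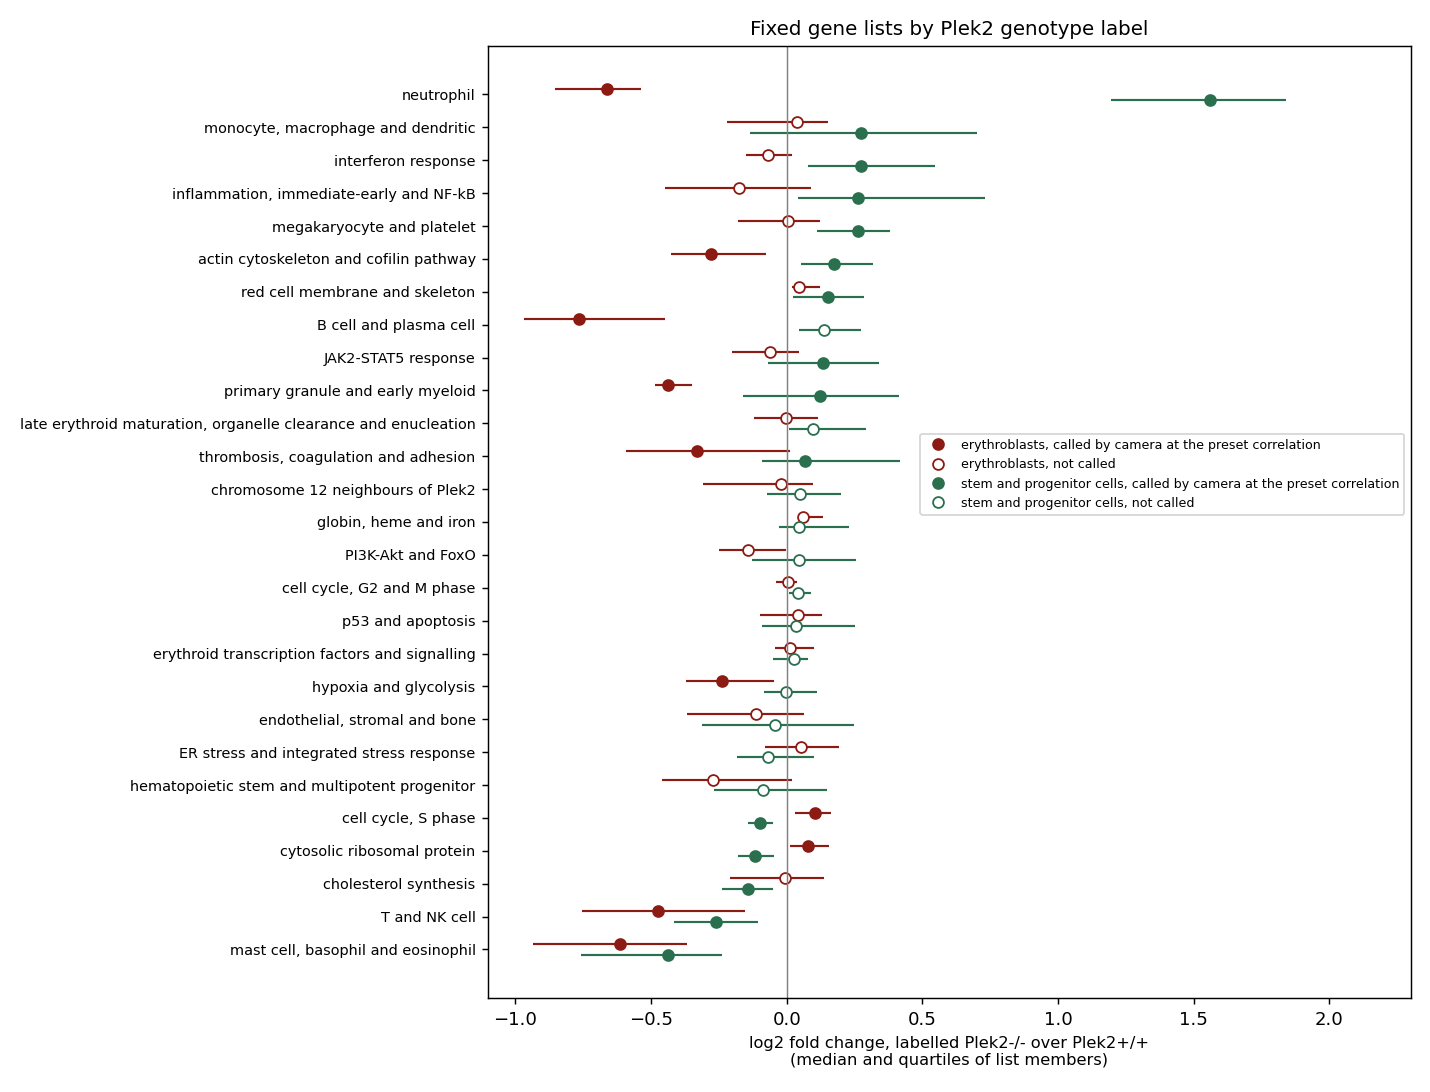
Log2 fold change of the 27 tested gene lists, libraries labelled Plek2-/- over Plek2+/+, in erythroblasts (red) and progenitors (green); points are medians of the list members, lines run between quartiles, and filled points were called by camera at its preset correlation (0 with an estimated one). Neutrophil genes lie at -0.66 in erythroblasts and 1.56 in progenitors, while several open points near 0 change sign with the scaling.

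The comparison of progenitors asks the same of the cells upstream. Here most called genes were higher in the libraries labelled Plek2-/-, among them 24 of 28 neutrophil, 11 of 34 inflammation, 11 of 40 interferon response and 8 of 34 JAK2-STAT5 genes. Camera called these 4 lists with its preset correlation but not with an estimated one (adjusted p = 0.569 each). The neutrophil granule gene Camp stood at 395 ± 192 CPM in libraries labelled Plek2+/+ and 1792 ± 436 CPM in those labelled Plek2-/- (SD, n = 2 each), and the chemokine receptor Cxcr2 at 68.5 ± 12.7 and 195 ± 10.4 CPM (SD, n = 2 each). In all, 646 of 13168 genes passed the edgeR test, 593 higher and 53 lower, of which 21 lie on X or Y. The change was over 2-fold in 199 of the higher and 7 of the lower genes. As in erythroblasts, each difference goes with sex as well as genotype.

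Of 28 neutrophil genes 24 rose and 0 fell in progenitors (25 adjusted over the list alone; median 1.56, quartiles 1.19 to 1.84, camera adjusted p = 2.43e-65, and 0.569 with an estimated correlation). Camp rose 4.54-fold (edgeR adjusted p = 0.00598), Lrg1 3.09-fold (edgeR adjusted p = 0.00112) and Cxcr2 2.86-fold (edgeR adjusted p = 0.000930). The list took 1.15% and 0.714% of counts in the Plek2+/+ libraries and 2.84% and 3.75% in those labelled Plek2-/-. Primary granule genes, which are abundant in early granulocyte progenitors, showed a smaller shift: 5 of 19 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.12, quartiles -0.16 to 0.42, camera adjusted p = 0.000488, and 0.569 with an estimated correlation). Csf3r, the receptor for granulocyte colony-stimulating factor, rose 2.43-fold from 128 ± 14.1 to 310 ± 29.9 CPM (SD, n = 2 each), and Cebpe rose 1.94-fold. Of 30 monocyte, macrophage and dendritic genes 5 rose and 1 fell (11 and 4 adjusted over the list alone; median 0.27, camera adjusted p = 0.00116, and 0.569 with an estimated correlation), with the antigen-presentation gene H2-Ab1 up 1.72-fold.

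**Figure D3:**
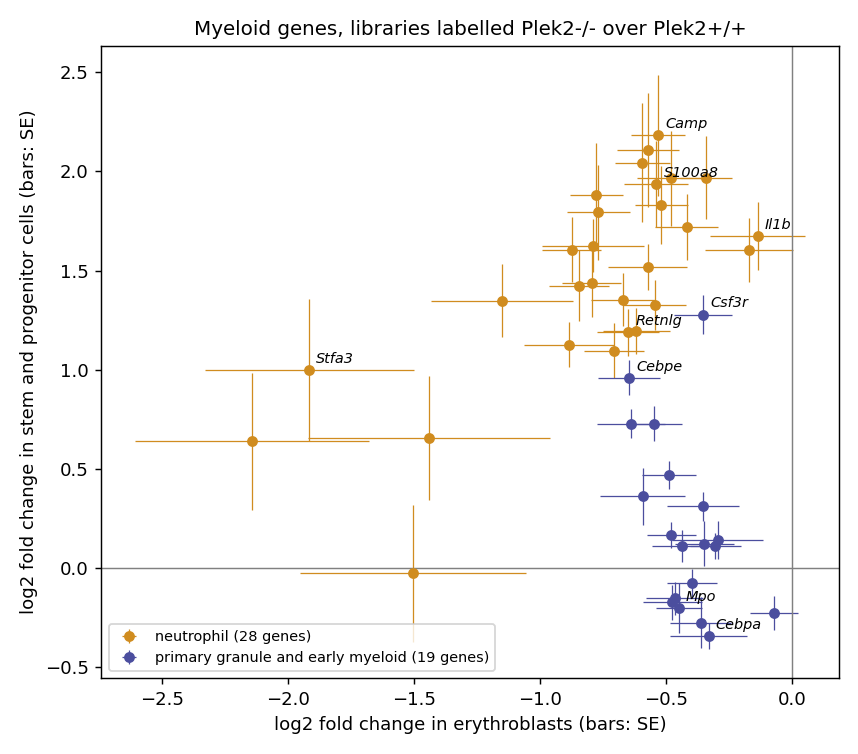
Log2 fold change in erythroblasts (horizontal axis) and progenitors (vertical axis), libraries labelled Plek2-/- over Plek2+/+, of 28 neutrophil genes (orange) and 19 primary granule genes (blue); each point is 1 gene and its lines are SEs. Both lists lie below 0 in erythroblasts (medians -0.66 and -0.44), while in progenitors neutrophil genes lie high (median 1.56) and primary granule genes on both sides of 0 (median 0.12).

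Some inflammatory and cytokine-response genes were called higher in progenitors beside the neutrophil genes (median 1.56). Of 34 inflammation, immediate-early and NF-kB genes 11 rose and 0 fell (17 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 9.74e-11, and 0.569 with an estimated correlation). Ptgs2 rose 4.72-fold from 4.51 ± 0.657 to 21.6 ± 1.34 CPM (SD, n = 2 each; edgeR adjusted p = 0.000525), and the immediate-early transcription factor Fos, a chromosome 12 gene, from 127 ± 1.06 to 254 ± 12.5 CPM (SD, n = 2 each). Of 40 interferon response genes 11 rose and 0 fell (15 and 2 adjusted over the list alone; median 0.27, camera adjusted p = 1.09e-07, and 0.569 with an estimated correlation). Among them the antiviral genes Oas2 and Rsad2 rose 2.09-fold and 1.82-fold. In the JAK2-STAT5 list, which holds Plek2, 8 of 34 rose and 0 fell (10 and 1 adjusted over the list alone; median 0.13, camera adjusted p = 0.000510, and 0.569 with an estimated correlation). Socs3, a feedback inhibitor of JAK signalling, rose 2.05-fold (edgeR adjusted p = 0.00154) and the cytokine gene Osm 1.72-fold (edgeR adjusted p = 0.00233).

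Some cytoskeletal, platelet and adhesion genes were also called higher in progenitors, where the neutrophil genes had a median of 1.56. Of 51 actin genes 12 rose and 0 fell (22 adjusted over the list alone; median 0.17, camera adjusted p = 3.81e-07, and 0.569 with an estimated correlation). The actin-severing protein gelsolin (Gsn) rose 2.03-fold and Vasp, which promotes filament elongation, 1.65-fold. Of 35 thrombosis and adhesion genes 8 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.07, or 0.0062 with library sizes only and 0.03 with the authors' size factors, camera adjusted p = 0.000438, and 0.569 with an estimated correlation). Its named members Itgam, at 2.29-fold, and Padi4, at 2.14-fold, are also in the neutrophil list. Of 30 megakaryocyte and platelet genes 5 rose and 0 fell (8 adjusted over the list alone; median 0.26, camera adjusted p = 0.000116, and 0.569 with an estimated correlation). Thbs1, thrombospondin-1, rose from 86.1 ± 9.51 to 164 ± 13.2 CPM (SD, n = 2 each), and the Plek2 paralog Plek, pleckstrin, rose 1.46-fold.

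Camera with its preset correlation called several lists lower in progenitors, and none with an estimated one. Mast cell, basophil and eosinophil genes had a median of -0.44, with 2 of 23 lower and 1 higher (6 and 1 adjusted over the list alone, camera adjusted p = 1.89e-05, and 0.569 with an estimated correlation). The basophil protease gene Prss34 fell from 662 ± 29.6 to 461 ± 28.6 CPM (SD, n = 2 each), whereas Hdc, which makes histamine, rose 1.55-fold. T and NK cell genes had a median of -0.26 (0 of 23 called by edgeR, 11 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom, 7 lower adjusted over the list alone, camera adjusted p = 0.000160, and 0.569 with an estimated correlation), with Il2rb at -0.35. S phase genes stood at -0.10 (0 of 32 called, 7 at an unadjusted p below 0.05, 0 by the other tools, 0 adjusted over the list alone, camera adjusted p = 0.00377, and 0.703 with an estimated correlation), with Mcm6 at -0.13. Ribosomal protein genes stood at -0.12 (0 of 73 called, 13 at an unadjusted p below 0.05, 0 by the other tools, 0 adjusted over the list alone, camera adjusted p = 0.000465, and 0.703 with an estimated correlation), with Rpl4 at -0.11. Cholesterol synthesis genes stood at -0.14 (24 tested, 1 fell; 1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.0162, and 0.703 with an estimated correlation).

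Red cell genes were not uniformly affected in progenitors. In the membrane list 2 of 26 rose and 0 fell (also 2 adjusted over the list alone; median 0.15, camera adjusted p = 0.0162, and 0.703 with an estimated correlation): beta-spectrin (Spnb1, on chromosome 12) up 1.86-fold and Cd24a, a surface protein also found on white blood cells, up 1.34-fold. Of 23 heme and iron genes 3 rose (also 3 adjusted over the list alone; median 0.05, camera adjusted p = 0.0527), among them the iron exporter Slc40a1, from 103 ± 8.41 to 207 ± 27.1 CPM (SD, n = 2 each), and heme oxygenase Hmox1, at 1.70-fold, both active in macrophages. Erythroid transcription factor genes had 0 of 25 called, 3 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom and 0 adjusted over the list alone (median 0.03, camera adjusted p = 0.874), with Myb at -0.14. Late maturation genes had 2 of 36 higher, Atg7 at 1.35-fold and Riok3 at 1.22-fold (6 adjusted over the list alone; median 0.10, camera adjusted p = 0.132). Medians of the heme and erythroid transcription factor lists change sign with library sizes only, and that of the transcription factor list also with the authors' size factors.

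Stem cell genes had a median of -0.09 in progenitors (34 tested, 2 higher; 5 adjusted over the list alone, camera adjusted p = 0.582), with Prom1 up 2.35-fold. In the stress lists, the cystine transporter Slc7a11 and Chac1 rose 2.67-fold and 3.17-fold (3 of 32; 3 rose and 2 fell adjusted over the list alone; median -0.07 with a mean of 0.07, camera adjusted p = 0.601). Gadd45a and Klf6 rose 1.89-fold and 1.46-fold in the PI3K-Akt and FoxO list (4 of 32; 7 rose and 2 fell adjusted over the list alone; median 0.05, camera adjusted p = 0.193). Plk2 and Fas rose 1.68-fold and 1.77-fold in the p53 list (4 of 35; 5 adjusted over the list alone; median 0.04, camera adjusted p = 0.236). G2 and M phase genes had 0 of 32 called, 1 at an unadjusted p below 0.05, 0 by the other tools and 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.551). These last 3 medians change sign with library sizes only, and that of the p53 list also with the authors' size factors. Igj was the 1 call of 23 B cell genes, at 2.58-fold higher (1 adjusted over the list alone; median 0.14, camera adjusted p = 0.0907). Acta2 rose 2.78-fold among 18 endothelial and stromal genes (2 rose and 2 fell adjusted over the list alone; median -0.04, camera adjusted p = 0.601). Vegfa rose 1.44-fold among 28 hypoxia genes (2 adjusted over the list alone; median -0.0015 with camera pointing up at adjusted p = 0.997).

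Among the largest single changes in progenitors, the acute-phase gene Orm1 rose 6.57-fold, the activin subunit gene Inhba 5.58-fold and the pseudogene Tmem181c-ps 4.62-fold. Among genes with a mean count of at least 20, as the rule for named genes asks, the largest falls outside Xist were Gpc4 (2.65-fold, on X), Tln2 (2.41-fold), Tctex1d1 (2.26-fold), Plekhh1 (2.18-fold), Stox2 (2.03-fold), Themis (1.93-fold), Stab2 (1.89-fold), Angptl2 (1.79-fold) and Nrg1 (1.72-fold). In all, 15 of 27 lists passed camera with its preset correlation, 0 with an estimated correlation and 0 with fry, whose lowest adjusted p was 0.215. The number of called genes was 440 and 239 without Plek2+/+ replicate 1 or 2, and 2649 and 1739 without replicate 1 or 2 labelled Plek2-/-; 36 of the 58 called genes that the rule picks in progenitors remained called without any 1 library. Without Plek2-/- replicate 2, camera no longer called the membrane (adjusted p = 0.508), S phase (adjusted p = 0.196), ribosomal (adjusted p = 0.177) and cholesterol (adjusted p = 0.131) lists, and it also lost the membrane list without Plek2+/+ replicate 1 (adjusted p = 0.0558) and the cholesterol list without Plek2+/+ replicate 2 (adjusted p = 0.271). Lists called only with 1 library left out were heme, late maturation, B cell, endothelial, PI3K-Akt and chromosome 12 neighbours, at adjusted p from 8.51e-05 for heme genes without Plek2-/- replicate 1 to 0.0452 for heme genes and chromosome 12 neighbours without Plek2+/+ replicate 2.

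Most genes called in both populations differed in opposite directions in erythroblasts and progenitors. Of 12009 genes tested in both, 129 were lower in erythroblasts and higher in progenitors labelled Plek2-/-, where independent lists would share 15.9 (odds ratio 16.1, two-sided Fisher's exact p = 4.06e-86). Fisher's test treats genes as independent, which they are not, so its p-values do not measure agreement between samples. The reverse combination held 0 genes (0.0898 by independence; Fisher's exact p = 1; 0 also with DESeq2 calls). Both populations were higher for 10 genes (1.07 by independence; Fisher's exact p = 2.61e-08), 4 of them Y-linked, and lower for 5 (1.33 by independence; Fisher's exact p = 0.0103). Without genes on X and Y, a choice made after the data were seen, these counts were 126 opposite, 6 higher in both and 3 lower in both, the last with Fisher's exact p = 0.107. The 9 autosomal genes that changed the same way in both were chosen by this criterion after their values were seen: Chac1, Igj, Ptgs2, Jkamp, Galc and Tjp1 rose, and Reln, Stx3 and Serpina11 fell. Across genes, which are not independent replicates, log2 fold changes in the populations had a Pearson r of 0.226 over all genes and -0.121 without X and Y. The Spearman rho was -0.0919 over all genes and -0.0950 without X and Y, so there was no strong opposition over all tested genes.

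The interaction test, which asks directly whether the genotype difference depends on the population, called 742 of 13365 genes, 31 with a higher and 711 with a lower effect in erythroblasts. Plek2 itself had the most negative value among named genes, at -3.66 (SE 0.26, edgeR adjusted p = 6.34e-05), followed by Slc6a12 at -3.18, Orm1 at -3.11, Foxd4 at -3.09 and Inhba at -2.97. On the positive side stood Cdkn1a at 1.09, Xist at 0.89 (a smaller fall, -9.52 in erythroblasts and -10.4 in progenitors), Lgmn at 0.88 and Gmpr at 0.70. Several of these calls were lost in some of the 8 fits with 1 library left out: Xist in 6, Gmpr in 5, and Cdkn1a and Foxd4 in 4 each. In those fits the values kept their sign: Xist stood at 0.81 to 0.92, Gmpr at 0.57 to 0.76, Cdkn1a at 0.85 to 0.99 and Foxd4 at -2.87 to -2.60. Among lists, neutrophil genes had a median interaction of -2.26, with 26 of 28 called lower (28 adjusted over the list alone, camera adjusted p = 1.09e-86). Camera called 15 of 27 lists, 13 lower and 2 higher, with a lowest adjusted p of 0.214 with an estimated correlation and 0.0612 with fry. The number of calls was 1175 without Plek2-/- erythroblast replicate 1 and 401 without Plek2+/+ progenitor replicate 2.

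Because a targeted allele can carry sequence of another strain around it, genes near Plek2 were examined. In progenitors, 17 of 156 tested genes within 10 Mb of Plek2 were called, 15 of them higher, or 10.9% against 4.85% of other autosomal genes, Plek2 left out (odds ratio 2.40, 95% confidence interval 1.35 to 4.02, two-sided Fisher's exact p = 0.00210). Within 5 Mb the share was 16.9% (10 of 59 genes), and regions of that smaller size were not compared elsewhere. Regions elsewhere held as large a share as the 10.9%: among 220 overlapping windows of 20 Mb on the autosomes with at least 40 tested genes, 40 to 60 Mb of chromosome 16 ranked highest (9 of 64, or 14.1%). Chromosome 12 held the windows ranked 2 (60 to 80 Mb, with Plek2 in it; 11 of 83, or 13.3%), 4 (90 to 110 Mb; 8 of 64, or 12.5%) and 6 (70 to 90 Mb, with Plek2 in it; 16 of 138, or 11.6%). Most calls in progenitors were higher anywhere in the genome, at 91.8%. Genes called in progenitors within 10 Mb of Plek2 did not share 1 direction across the populations. Several had the opposite sign in erythroblasts, such as Arg2 (1.74 in progenitors and -0.69 in erythroblasts), Pygl (0.93 and -0.58) and Jdp2 (0.49 and -0.77). Others had the same sign, such as Jkamp (0.56 and 0.96) and Spnb1 (0.90 and 0.27). In erythroblasts 7 of 148 were called, or 4.73% against 2.82% (odds ratio 1.71, Fisher's exact p = 0.203). Among 212 such windows in erythroblasts, 140 to 160 Mb of chromosome 1 ranked highest (5 of 50) and chromosome 12 held those ranked 2 (90 to 110 Mb; 6 of 62, or 9.68%) and 3 (60 to 80 Mb; 6 of 78, or 7.69%, level with a window of chromosome 15). The fixed list of neighbours had 7 of 52 higher and 2 lower in progenitors (10 and 3 adjusted over the list alone; median 0.05, which changes sign with library sizes only, camera adjusted p = 0.0694), led by the arginase gene Arg2, up 3.33-fold (edgeR adjusted p = 0.000925), and the retinol dehydrogenase gene Rdh12, up 2.25-fold. In erythroblasts 1 of 51 was lower, Fntb at 1.45-fold (5 adjusted over the list alone; median -0.02, camera adjusted p = 0.124). Across the whole of chromosome 12, 13 of 399 genes had an unadjusted p below 0.05 and the same sign in both populations, or 3.26% against 1.26% of other autosomal genes (odds ratio 2.63, Fisher's exact p = 0.00261). This count was chosen after the data were seen. Among these is Galc, a lysosomal galactosylceramidase gene from 98202294 to 98259459, with log2 fold changes of 0.89 and 0.90, and Jkamp, from 72085589 to 72101461, with 0.96 and 0.56. Serpina11, from 103980243 to 103989957, had -4.77 and -3.67 on low counts.

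**Figure D4:**
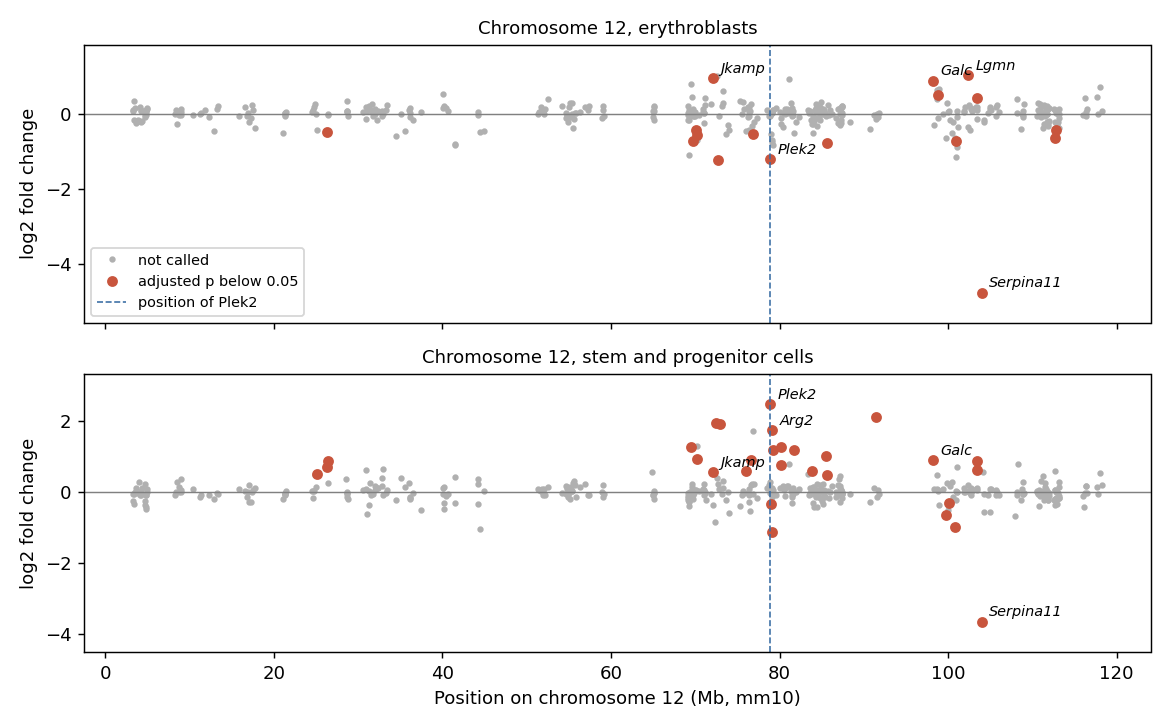
Log2 fold change, libraries labelled Plek2-/- over Plek2+/+, of each tested chromosome 12 gene by position (Mb, mm10) in erythroblasts (top) and progenitors (bottom); red points have an edgeR adjusted p below 0.05 and the dashed line marks Plek2. Within 10 Mb of Plek2, 17 of 156 genes were called in progenitors and 7 of 148 in erythroblasts.

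The comparison of Plek2+/+ erythroblasts with Plek2+/+ progenitors describes what the sorted populations hold. Most red cell genes were higher in erythroblasts and most stem cell, T and NK cell genes higher in progenitors, though camera called 0 of these lists with an estimated correlation (lowest adjusted p = 0.103). In this comparison fry called 22 of 27 lists (lowest adjusted p = 2.09e-05), and camera with its preset correlation called 16. The heme-forming enzyme gene Fech was 51.7-fold higher in erythroblasts, the Rh antigen gene Rhd 57.8-fold, the erythroid transcription factor gene Sox6 146-fold and Bpgm, which makes the red cell regulator of oxygen binding, 129-fold. The stem cell antigen gene Cd34 was 10.1-fold lower in erythroblasts. In all, 9865 of 13365 genes were called, 4818 higher and 5047 lower in erythroblasts, and Plek2 was among the higher ones (log2 fold change 6.90, SE 0.19, edgeR adjusted p = 3.17e-12). On the TMM scaling of all 8 libraries behind this value, Plek2 stood at 118 CPM in Plek2+/+ erythroblasts and 1.03 CPM in Plek2+/+ progenitors. In libraries labelled Plek2-/- it stood at 50.6 CPM in erythroblasts and 5.36 CPM in progenitors. The value thus rests on the low level of the progenitors labelled Plek2+/+.

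By list, 24 of 25 heme and iron genes were higher in erythroblasts (median 3.89, camera adjusted p = 4.47e-32, and 0.112 with an estimated correlation). The membrane list had 23 of 26 higher and 2 lower (median 4.24, camera adjusted p = 8.64e-41, and 0.112 with an estimated correlation). Late maturation genes had 30 of 36 higher and 3 lower (median 2.75, camera adjusted p = 1.58e-42, and 0.103 with an estimated correlation). G2 and M phase genes were higher in 32 of 32 (median 1.80, camera adjusted p = 2.60e-17, and 0.322 with an estimated correlation). T and NK cell genes were lower in 22 of 23 and higher in 1 (median -2.79, camera adjusted p = 1.73e-07, and 0.281 with an estimated correlation), with Il2rb 9.98-fold lower. Of 28 neutrophil genes 27 were higher in erythroblast libraries labelled Plek2+/+ (median 1.30, camera adjusted p = 0.0170, and 0.727 with an estimated correlation), with S100a8 at 5078 ± 533 against 1308 ± 426 CPM (SD, n = 2 each). In libraries labelled Plek2-/- the order was opposite: S100a8 stood at 3470 ± 164 CPM in erythroblasts and 4867 ± 843 CPM in progenitors (SD, n = 2 each), and the list took 1.22% ± 0.0976 and 3.30% ± 0.637 of counts (SD, n = 2 each). Primary granule genes went the other way, with 13 of 19 lower and 2 higher (median -1.08, camera adjusted p = 7.64e-05, and 0.322 with an estimated correlation), and the myeloperoxidase gene Mpo was 7.48-fold lower. Scaling by library sizes only lowers the median of all genes by 0.81 on the log2 scale, so these values are relative to the scaling.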

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

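The differences listed here were found by the planned interaction test; all tests that weigh an explanation for them were chosen after the results were seen. Each value is a genotype effect in erythroblasts minus that in progenitors, on the log2 scale, for genes and lists whose effects differed between the populations.

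Plek2 differed most among the named genes, at -3.66: libraries labelled Plek2-/- held fewer Plek2 reads in erythroblasts and more in progenitors. Erythroblasts carried into the progenitor libraries are argued against: 53 abundant erythroblast genes imply a median share of 0.0998% (quartiles 0.0539 to 0.202%), whereas the Plek2 reads would need 8.55%, and 0 of the 53 reach it. TER119-negative erythroid cells were not examined in this way. Swapped genotype labels among the progenitor libraries stay an open explanation. A swap alone would put genes that respond the same way to genotype in both populations in opposite directions. The sex pattern followed the genotype label in both populations, so effects of sex would keep their direction with or without a swap. There were 9 autosomal genes called in the same direction in both populations, against 125 called in opposite directions. These counts do not decide it. Sex could give the same direction, and neutrophil genes, for which another candidate explanation is given below, also ran in opposite directions. With swapped progenitor labels, Plek2-/- libraries would be male in erythroblasts and female in progenitors, which the labels do not settle. Transcription from the targeted allele is a further open explanation, which was not tested because the deleted part is not stated and counts per gene do not show where reads lie.

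Neutrophil genes had the largest list difference, at a median of -2.26 (camera adjusted p = 1.09e-86, and 0.214 with an estimated correlation), with Stfa3 at -2.89, Camp at -2.68, Lcn2 at -2.63, Ifitm6 at -2.45, Lrg1 at -2.38, Cxcr2 at -2.06, Itgam at -1.78 and Padi4 at -1.77. A candidate explanation is a different share of neutrophils in the libraries, lower in erythroblast and higher in progenitor libraries labelled Plek2-/-: between the progenitor libraries of 1 genotype, 96.2% (Plek2+/+) and 92.3% (Plek2-/-) of 26 other neutrophil genes followed S100a8 and S100a9, as did 80.9% and 81.9% of 554 other autosomal genes that rose in progenitors, against 48.8% and 50.4% of genes not called. Between the Plek2+/+ erythroblast libraries, 100% of these 26 genes followed. Other autosomal genes that fell did so there at 59.5% (299 genes), and genes not called at 47.7%. Between those labelled Plek2-/- the same shares were 92.3%, 88.6% and 50.4%. There S100a8 and S100a9 themselves differed by only 0.075 on the log2 scale, against a median of 0.333 for the 26 genes. The direction set by S100a8 and S100a9 is therefore uncertain in that pair of libraries. Outside the Plek2+/+ erythroblasts the pattern between libraries is thus not confined to neutrophil genes, and shared regulation would give it as well. The TER119-positive selection and the Kit-positive selection from lineage-negative cells would each be expected to remove neutrophils. More early granulocyte progenitors as the whole cause is argued against, because the primary granule genes had a median of 0.12 in progenitors where neutrophil genes had 1.56. Sex cannot be told apart from genotype, since it followed the label in 8 of 8 libraries, and an effect of Plek2 on neutrophil production stays open and was not tested.

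Chromosome 12 neighbours of Plek2 had a median difference of -0.037, with a negative camera call (camera adjusted p = 0.0124, and 0.420 with an estimated correlation). Among named genes of the chromosome, in or outside that list, Arg2 stood at -2.39, Rdh12 at -1.98, Dhrs7 at -1.42, Fos at -1.02 and Lgmn at 0.88. Apart from these, 13 of 399 chromosome 12 genes had an unadjusted p below 0.05 and the same sign in both populations (3 were called in both by edgeR), or 3.26% against 1.26% elsewhere, and the next highest chromosome, chromosome 1, had 2.01%. Sequence of another strain carried along with the targeted allele may be a source, but the 13 genes lay a median of 20.8 Mb from Plek2 against 23.7 Mb for all tested genes of the chromosome (one-sided permutation p = 0.290), which does not decide it. Sex cannot be told apart from genotype here either, in 8 of 8 libraries.

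Further myeloid and inflammatory genes with a lower effect in erythroblasts were Orm1 (-3.11), Inhba (-2.97), Csf3r (-1.60), Plaur (-1.58), Cebpe (-1.58), Serpinb1a (-1.24), Hdc (-1.25), Osm (-0.89) and Slc40a1 (-0.96). The lists with a lower median effect were B cell (-0.88), inflammation (-0.57), thrombosis (-0.52), primary granule (-0.44), actin (-0.41), megakaryocyte (-0.34), interferon (-0.30), monocyte (-0.25), PI3K-Akt (-0.14), JAK2-STAT5 (-0.12) and hypoxia (-0.10). Those with a higher median effect were ribosomal protein genes (0.25) and S phase genes (0.22). Of the 15 lists that camera called, 0 were called with an estimated correlation (lowest adjusted p = 0.214). That setting also called 0 lists between the populations, where 24 of 25 heme genes were higher, so its lack of calls does not decide here. Fry, which called 22 of 27 lists between the populations, also called 0 for the interaction (lowest fry adjusted p = 0.0612). Neutrophil genes had an estimated correlation of 0.745, far above the preset 0.01, so their camera p-value at the preset can be far too small.

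Signalling and stress genes with a lower effect in erythroblasts were Fas (-1.80), Socs3 (-1.24), Slc7a11 (-1.17), Oas2 (-1.11), Plk2 (-1.04), Rsad2 (-0.86), Vegfa (-0.78), Gadd45a (-0.76), Klf6 (-0.70), Il4ra (-0.64) and Atg7 (-0.58). Cytoskeletal and metabolic genes were Gsn (-1.54), Vasp (-1.11), Coro1a (-0.77), Rac2 (-0.77), Hk2 (-0.77), Pkm2 (-0.76) and Plek (-0.72). Others were Slc6a12 (-3.18), Foxd4 (-3.09), Tmem181c-ps (-2.66), Mcam (-2.57), Acta2 (-1.91), Prom1 (-1.66), Blk (-1.31), Emid1 (-1.101) and Rag1 (-0.87). A higher effect in erythroblasts was found for Cdkn1a (1.09) and Gmpr (0.70). Xist (0.89) fell in both populations, by slightly less in erythroblasts (-9.52) than in progenitors (-10.4).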

How the results depend on the processing

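Plek2 kept its direction and its call in 17 of 17 alternatives in erythroblasts (log2 -1.33 to -1.11), 17 of 17 in progenitors (2.02 to 2.96) and 16 of 16 for the interaction (-4.14 to -3.20). Within each population the fold minimum and leaving out X and Y reuse the main fit. Plek2 could not change direction or, at its values, lose its call in these settings. Numbers of called genes moved more. For erythroblasts (348) they were 230 with library sizes only, 547 with the authors' size factors, 845 with no low-count filter, 579 with the replicate block, 42 with a log2 fold change of at least 1, and 25 to 995 with 1 library left out. For progenitors (646) they were 1315 with no filter, 206 with that fold minimum, 1327 with the crossed replicate block chosen after seeing the data (813 with the numbered one), and 239 to 2649 with 1 library left out; with library sizes only the split was 527 higher and 133 lower. The interaction (742) gave 1215 with no filter and 401 to 1175 with 1 library left out, and the overlap (144) gave 233 with the replicate block. The fold minimum calls fewer by construction; for the others the cause was not tested. Of 40 calls that the rule for named genes picks in erythroblasts, 5 were lost with library sizes only, 3 with DESeq2 among the 33 it tested, and 1 with limma-voom. Of 58 in progenitors, 1, 4 and 1 were lost. With 1 library left out, 1 residual degree of freedom remains within a population, and the lone sample is assumed to vary like the other group.

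Lists called in erythroblasts (10) and progenitors (15) fell to 0 and 0 with an estimated correlation and to 0 and 0 with fry, and numbered 9 to 18 and 11 to 21 with 1 library left out. Over those fits in erythroblasts, camera adjusted p ran from 0.00183 to 0.212 for megakaryocyte genes (opposite direction at 0.00206 without Plek2+/+ replicate 1), from 4.07e-06 to 0.727 for interferon genes (opposite at 0.0190 without Plek2-/- replicate 2) and from 0.00196 to 0.132 for G2 and M phase genes (opposite at 0.0415 without Plek2+/+ replicate 1). In the population contrast, Rplp1 (-0.048) and Rpl7 (-0.12) reversed with library sizes only, which moves the median of all genes by -0.81, and Xist (0.24) reversed with both genotypes averaged, which adds libraries with almost no Xist. The cause of the other reversals was not tested. Windows of 5 and 20 Mb around Plek2 gave odds ratios of 3.99 and 2.33 in progenitors (Fisher's exact p = 0.000548 and 0.00142) and 0.588 and 1.93 in erythroblasts (Fisher's exact p = 1 and 0.0610). With 2 libraries per group, simulated changes of 1.5-fold were recovered at 68.7% in erythroblasts and 76.1% in progenitors, so smaller changes are often missed.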

Other observations

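Lists not described above for Plek2+/+ erythroblasts against Plek2+/+ progenitors show what else the sorted populations hold. Monocyte, macrophage and dendritic genes were mixed but mostly higher in erythroblasts (19 of 30 higher and 9 lower; median 1.37, camera adjusted p = 4.53e-06, and 0.322 with an estimated correlation). The complement genes C1qa and C1qc, which are typical of macrophages, were 53.6-fold and 56.6-fold higher. Interferon response genes had 25 of 40 higher and 9 lower (median 0.77, or -0.05 with library sizes only, camera adjusted p = 0.0171, and 0.727 with an estimated correlation), with Rsad2 165-fold and Isg15 84.3-fold higher. S phase genes had 29 of 32 higher and 1 lower (median 1.16, camera adjusted p = 1.67e-09, and 0.322 with an estimated correlation). Erythroid transcription factors and signalling genes had 16 of 25 higher and 8 lower (median 1.84, camera adjusted p = 8.70e-06, and 0.297 with an estimated correlation), and the erythropoietin receptor gene Epor was 11.8-fold higher. Integrated stress response genes had 17 of 32 higher and 12 lower (median 0.27, which changes sign with library sizes only, camera adjusted p = 0.0104, and 0.322 with an estimated correlation), with Trib3 294-fold and the asparagine synthetase gene Asns 9.22-fold higher.

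Progenitors held more of several other programs. Stem cell genes had 27 of 34 lower in erythroblasts and 3 higher (median -1.38, camera adjusted p = 3.79e-05, and 0.297 with an estimated correlation). Mast cell, basophil and eosinophil genes had 12 of 23 lower and 1 higher (median -0.68, camera adjusted p = 7.64e-05, and 0.322 with an estimated correlation), with the basophil protease genes Prss34 and Mcpt8 9.43-fold and 8.11-fold lower. Inflammation and immediate-early genes had 21 of 34 lower and 7 higher (median -0.74, camera adjusted p = 0.00591, and 0.322 with an estimated correlation), with Jun 6.28-fold lower. B cell genes had 16 of 23 lower and 1 higher (median -0.67, camera adjusted p = 0.0429, and 0.727 with an estimated correlation). The JAK2-STAT5 list was split, 14 of 33 higher and 14 lower, with the survival gene Bcl2l1 higher in erythroblasts by 4.91 on the log2 scale and the erythroferrone gene Fam132b 43.4-fold higher.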
